A study of Solanum pimpinellifolium with 4 samples.

How the data were processed

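Messenger RNA was sequenced from shoot tips that carried 1 small visible leaf, taken from 45-day-old plants of *Solanum pimpinellifolium* LA1589, a small-fruited wild relative of cultivated tomato. The 4 libraries were 2 transgenic lines, 103 and 104, labelled as carrying HA-tagged SlZFP2 (a zinc finger protein) behind the strong 35S promoter, and a nontransgenic sibling of each line. Libraries were paired-end and run on a HiSeq instrument, per the labels' protocols.

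The deposited table gives 1 FPKM value (fragments scaled by the transcript's length and the library's number of fragments) per annotated transcript and library, as the authors made it. TopHat 1.3.2 and Cufflinks are named in the submitters' processing notes, with no role or order, and the settings are not given in the sources used here. Per the file headers, coordinates are on the SL2.40 tomato build, and each locus has a functional description, from which names were taken. The reference table given for gene names is of another assembly and matched 0 of the identifiers, so it was not used. Of 34727 rows, 2 had shifted columns and no expression values and were left out.

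Values were compared as log2(FPKM + 1), so fold changes are on that scale and understate the change of weakly expressed genes. Genes with at least 1 FPKM in at least 2 libraries were tested, 20433 in all. The main test was limma-trend (limma 3.58.1, R 4.3.3), transgenic against sibling, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, adjusted over the 29 lists so tested. An identifier whose annotation did not match the text expected for it was left out of its list, which removed 5 loci (SFT, AN, MC, BRC1a and BRC1b). Genes were named by a rule fixed beforehand: SlZFP2, the 10 largest and 10 smallest fold changes among annotated genes that passed and moved the same way in both lines (all of them where fewer passed; where fewer than 5 passed, the 5 with the smallest p), and up to 4 members of each list with the smallest p. All tested members of the ABA synthesis, florigen family and flowering lists were open to naming. Named outside the rule are SFT, which was removed from its list, and TM6 and Solyc11g027630, chosen after their values were seen.

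The line number pairs the samples by descent, since each sibling comes from the family of its line. Deviations of the 2 libraries of a line from their group means correlated at 0.23 across genes. A fit with the line as block was planned as an alternative and leaves 1 residual degree of freedom, against 2 without it. Nothing in the labels says how many plants made up a library, so the spread behind the p-values is between these 4 libraries, not between plants. The limma p-values also draw on variance shared across genes. Camera at the preset correlation treats the genes of a list as nearly independent.

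Because the table holds FPKM and no counts, depth was read from the step sizes. For transcripts of at least 500 bp the value of 1 fragment depends on the spliced length, an effective-length offset and the library's number of fragments. Fitting the last 2 gave 8612583 and 8725917 fragments for the line 103 transgenic and sibling libraries, and 10601280 and 10384385 for those of line 104. A spliced length was then sought for each transcript that made every nonzero value a whole number of fragments within 0.01. A single length did so for 14640 tested transcripts (71.6%). Those with at least 10 fragments in at least 2 libraries, 14286 genes, were tested with limma-voom, with and without the line as block. This alternative was chosen after seeing the data. It leaves out many genes that are listed at 0 in several libraries, since their length cannot be fixed. The limit on chance solutions (0.2 expected per transcript) was set after seeing how many transcripts it kept. At 0.05, 13296 genes were tested, and the fit with the block gave 80 higher and 108 lower.

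Fragments of transcripts under 500 bp were read from values that recur among genes of equal length. That gave fragments for 12 of the 27 genes called by the main test, and the reading of longer transcripts for 1 more, 13 in all (48.1%). Looser reading rules were tried after this share was seen, to raise it, and are not used.

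The fits were tested on simulated data for the transgenic against sibling comparison, with 200 changed genes. The simulated genes were modelled on those with recovered fragments, at least 10 in at least 2 libraries. False calls among short transcripts at a few fragments, such as those in the main calls, were therefore not simulated. With line differences and a coefficient of variation of 0.2 that itself varied between genes, limma-trend on 14188 genes recovered 46 of 50 genes changed 16-fold and 0 of 50 changed 2-fold, with 5 false calls. With the same settings limma-voom with the block recovered 41 of 50 and 0 of 50 of 14189 genes tested, with 1 false call. At a coefficient of 0.1 that varied likewise, it made 9 false calls, 5.2% of its calls. Where the variation was the same for all genes, false calls made up 4.5% and 7.1% of the calls of that fit at coefficients of 0.1 and 0.2. For limma-trend on FPKM with the block, the fit behind the blocked FPKM counts, they made up 18% and 8.6%, on 14222 and 14204 genes. Each simulated gene had the same change in both lines. Differences between the lines' changes, which the residual of a blocked fit holds, were therefore not simulated. The shares of false calls of the blocked fits need not hold for the real data.

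Alternatives were quantile normalization, no filter, a filter of 5 FPKM, the block, a pseudocount of 0.1, limma without trend, a 2-fold threshold, an estimated inter-gene correlation, fry, Spearman's correlation and leaving out each library. Added after seeing the data were the recovered fragments, a minimum gene region of 500 bp, and a test of the difference between the lines' changes as a contrast of 2 libraries against 2, whose residual holds the genotype and line effects.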

Results

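The expression of 34725 annotated tomato transcripts was compared between shoot tips of 2 lines labelled as p35S:HA-SlZFP2 transgenics and shoot tips labelled as their nontransgenic siblings, with 2 libraries in each group. Transgenic and sibling are used here as the labels give them. The series names abscisic acid, growth, flowering and the SINGLE FLOWER TRUSS pathway as its subject. The libraries held 8612583 to 10601280 fragments, as read from the step sizes of the FPKM values.

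The question of whether the transgene raised its own transcript was addressed first. The locus fixed beforehand as SlZFP2, Solyc07g053570 (chromosome 7, 59307855 to 59310428), was at 3.18 and 4.11 FPKM in the transgenic libraries of lines 103 and 104 and at 2.59 and 3.53 FPKM in their siblings. Its log2 fold change was 0.20 (SE 0.29), and it did not pass (limma-trend, adjusted p = 0.9993). A different zinc finger gene, Solyc07g006880 (annotated Zinc-finger protein 1, chromosome 7, 1742040 to 1742531), was at 3095 and 2641 FPKM in the transgenic libraries and at 2.14 and 1.24 FPKM in the siblings. It rose by 10.07 on the log2 scale (SE 0.28, limma-trend adjusted p = 0.00146). Without the transgenic library of line 103 its adjusted p was 0.0548. The table pairs neither locus with the name SlZFP2. The identifier Solyc07g053570 came from background knowledge, not from the table or the labels, and may be the wrong gene, in which case its 0.20 says nothing of the transgene. Solyc07g006880 was singled out after its values were seen, as the gene with the largest rise of those tested. Its values separate the 4 libraries as the labels do, at 1450-fold and 2122-fold the sibling level in lines 103 and 104. Whether this locus is SlZFP2, and its values those of the transgene's transcript, is not settled by the sources used here. The planned label check needs the right locus and so stays open.

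Genes that specify floral organs were higher in both transgenic libraries. All 8 members of the floral organ identity list were higher in both lines, and the list was higher as a group (camera, adjusted p = 1.14e-15; adjusted p = 0.608 with an estimated correlation). The median log2 fold change was 2.46 in line 103 and 1.89 in line 104. TAP3, a B-class MADS-box gene of petals and stamens, was at 87.7 ± 34.2 FPKM in transgenic and 10.3 ± 7.23 FPKM in sibling tips (SD, n = 2), a log2 fold change of 3.08 (SE 0.56). TPI, also of the B class, had a log2 fold change of 2.47 (SE 0.45), GLO2, of the same class, 1.89 (SE 0.47), and TM5, a SEPALLATA-type gene, 2.29 (SE 0.46). Adjusted over the list alone, 8 of 8 members passed, and over all genes tested 0 passed in limma-trend. TM6, named outside the rule after its values were seen, had the smallest ratio, 3.05-fold in line 103 and 1.95-fold in line 104.

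**Figure D1:**
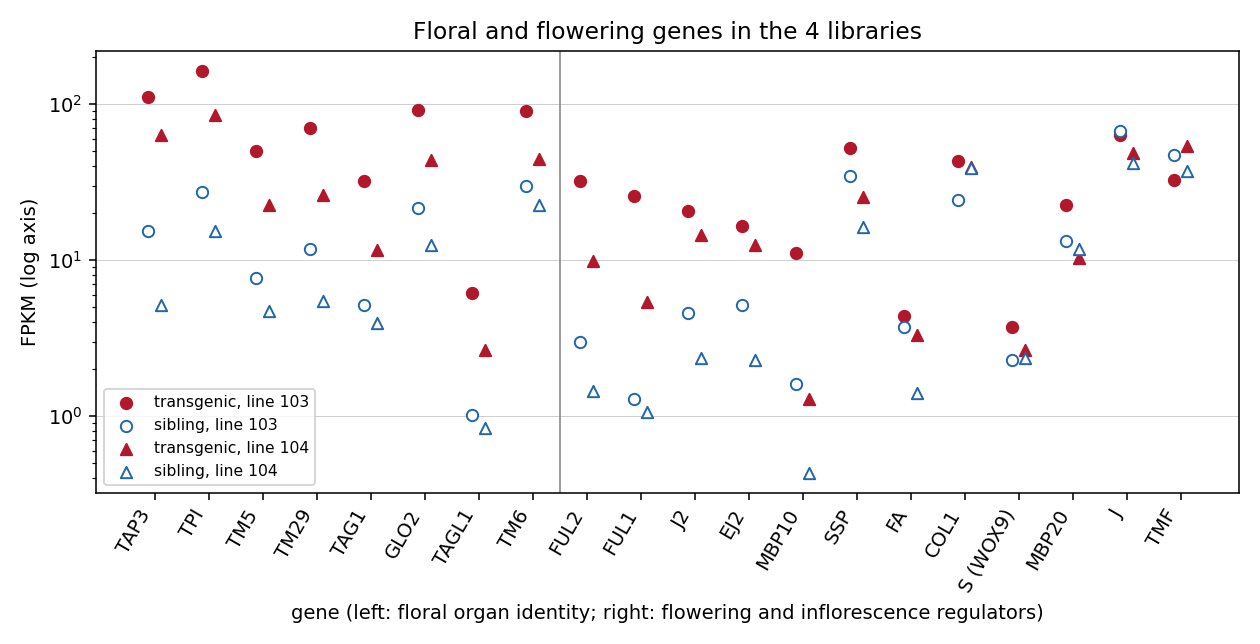
FPKM (log axis) of the 8 floral organ identity genes and 12 flowering and inflorescence regulators in each of the 4 libraries; filled red symbols are transgenic and open blue symbols sibling libraries, circles line 103 and triangles line 104. Each of the 8 floral organ identity genes was higher in the transgenic library than in its sibling in both lines, while J and TMF were lower in line 103 and higher in line 104.

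The flowering and inflorescence regulators were also higher as a group (12 tested, camera adjusted p = 3.8e-08; adjusted p = 0.608 with an estimated correlation), with 9 members higher in both lines and 0 lower in both. Adjusted over the list alone 4 passed, and over all genes 0. These were the MADS-box genes J2 (17.5 ± 4.36 against 3.46 ± 1.58 FPKM, SD, n = 2), EJ2 (14.5 ± 2.80 against 3.71 ± 2.03), FUL2 (21.0 ± 15.8 against 2.22 ± 1.10) and FUL1 (15.5 ± 14.3 against 1.18 ± 0.16). J2 and EJ2 act in inflorescence branching, and FUL1 and FUL2 are FRUITFULL homologs. JOINTLESS (J) and TMF had log2 fold changes of 0.06 and -0.00. The wider MADS-box list of 45 genes, which shares 8 genes with the floral organ identity list and 7 with the flowering list and so is not independent of them, was higher (adjusted p = 3.6e-07; adjusted p = 0.647 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. With the line as block these counts were 14 and 2, and over all genes 0 passed in either fit. Of the 45 genes, 18 were higher and 10 lower in both lines. The 18 include all 8 floral organ identity genes. The 10 lie outside both smaller lists, which had 0 members lower in both lines. The call of the wider list therefore does not show a rise of MADS-box genes beyond the shared ones.

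SFT, the tomato florigen gene, was below the filter and is named outside the rule, as the gene of the pathway in the series' subject. Its locus, annotated SELF PRUNING 3D (chromosome 3, 30564833 to 30568648), was at 0.429 and 0.349 FPKM in the transgenic libraries and listed at 0 in both siblings. These values equal 1 fragment each for a spliced length of 534 bp, so a difference in SFT was not detectable at this depth. Of the florigen family 2 members were tested. SP, a repressor of flowering, was at 1.67 ± 0.12 FPKM in transgenic and 2.92 ± 0.04 FPKM in sibling tips (SD, n = 2), and SP5G had a log2 fold change of -0.11. Neither passed.

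The genes of abscisic acid synthesis were not called as a group (7 tested, camera adjusted p = 0.933). Of these, 1 was higher and 2 were lower in both lines, and the list median was 0.36 in line 103 and -0.42 in line 104. The test looks for a shared direction, so it cannot show that these genes did not differ. NCED1, which encodes a rate-limiting enzyme of the pathway, was at 8.89 and 8.98 FPKM in the transgenic libraries of lines 103 and 104 and at 4.09 and 5.93 FPKM in their siblings, a log2 fold change of 0.74 (SE 0.26), and AO1, an aldehyde oxidase gene, had one of -0.78 (SE 0.28). Adjusted over the list alone, 0 of the 7 passed (limma-trend; 2 had an unadjusted p under 0.05). The lists of ABA signalling (adjusted p = 0.864) and LEA and dehydrin genes (adjusted p = 0.864) were not called either. On recovered fragments with the block, 1 ABA signalling gene rose and 1 fell over all genes. These were a protein phosphatase 2C gene, Solyc06g051940 (limma-voom adjusted p = 0.0205, 0.999 without the block), and the receptor gene Solyc10g076410 (0.0176, 0.788 without it). CYP707A2, of ABA breakdown, was lower in that blocked fit, with 0.0331 over its list alone and 0.325 over all genes.

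Meristem and branching genes were higher as a group (6 tested, adjusted p = 0.000503; adjusted p = 0.608 with an estimated correlation; 0.0513 without the transgenic library of line 103). WUS, which maintains stem cells in the meristem, was at 2.66 and 1.78 FPKM in the transgenic libraries and at 0.472 FPKM in the line 103 sibling, and was listed at 0 in the line 104 sibling. Photosynthesis genes were higher by a median of 0.26 in line 103 and 0.27 in line 104 (127 tested, adjusted p = 3.64e-06; adjusted p = 0.482 with an estimated correlation; 0.134 without the sibling library of line 104). Gibberellin genes (45 tested, adjusted p = 0.00098) and auxin response genes (84 tested, adjusted p = 0.00122) were higher too, and both had an adjusted p of 0.482 with an estimated correlation. The gibberellin list had an adjusted p of 0.0591 at a filter of 5 FPKM. The auxin list had one of 0.165 without the transgenic library of line 104, 0.277 without the sibling of line 103, and 0.0706 on recovered fragments with the line as block. For gene regions of at least 500 bp it was 0.0618, and 0.0925 with the block.

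Defence and pathogenesis-related genes were lower as a group (118 tested, adjusted p = 0.000287; adjusted p = 0.608 with an estimated correlation; 0.361 without the transgenic library of line 103), with 57 lower and 17 higher in both lines. The chitinase-like gene Solyc07g005100 fell from 44.8 ± 0.16 FPKM in sibling to 8.97 ± 1.28 FPKM in transgenic tips (SD, n = 2) and was the 1 member that passed adjusted over the list alone. Over all genes it did not pass on FPKM (limma-trend adjusted p = 0.123), and passed on recovered fragments without the block (limma-voom adjusted p = 0.0316) and with it (6.89e-09). The list's change differed between the lines, with a median of -0.36 in line 103 and -0.15 in line 104 (camera adjusted p of the difference = 0.0182; adjusted p = 0.97 with an estimated correlation). Genes of the cyclins and mitosis list were lower (110 tested, adjusted p = 0.00618; adjusted p = 0.714 with an estimated correlation), with 46 lower and 9 higher in both lines. The list's text pattern also matched genes annotated as cyclin-dependent, so it is not limited to cyclins and kinesins. A cyclin-dependent kinase inhibitor gene in it, Solyc01g108610, was higher in both lines (2.02-fold and 2.35-fold). The change of the list's genes also differed between the lines, with medians of -0.08 and -0.35 (adjusted p of the difference = 0.013; adjusted p = 0.971 with an estimated correlation). Their adjusted p was 0.245 without the transgenic and 0.594 without the sibling library of line 104, and 0.0661 with no filter. In all, 11 of 29 lists were called at the preset correlation, and 0 with an estimated correlation (13 had an unadjusted p under 0.05 at the preset one) or with fry. The estimated correlation rests on 2 residual degrees of freedom, so the calls lost with it do not show that the lists did not differ.

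Over single genes, limma-trend called 17 higher and 10 lower of 20433. At an unadjusted p under 0.05 there were 687, a smaller share than that threshold alone would give with no differences. The split of the 4 libraries that crosses genotype and line, which holds no common genotype effect, called 29. The genotype count did not exceed it. Besides Solyc07g006880, the annotated genes called higher were Solyc06g076870, a 60S acidic ribosomal protein P0 gene (17.2 ± 0.44 against 1.10 ± 0.15 FPKM, SD, n = 2; adjusted p = 0.0454, and 0.0667 with the line as block; limma-voom adjusted p = 0.0316 on recovered fragments), and 3 genes listed at 0 in both siblings, annotated as elongation factor 1-alpha, diaminopimelate decarboxylase 2 and Avr9/Cf-9 rapidly elicited protein 146. Those called lower were listed at 0 in both transgenic libraries and were annotated LUMINIDEPENDENS, BED finger NBS-LRR protein and Ninja-family protein 2. The Avr9/Cf-9 146, BED finger and Ninja calls each rest on 1 fragment in each library of the group that is not at 0, so, as for SFT, a difference in these genes was not detectable at this depth. Fragments could not be read for the other 3 genes listed at 0. Of the 27 genes, 25 were listed at 0 in both libraries of 1 group, 19 lay in regions under 500 bp and 19 were annotated as unknown proteins. Without the transgenic library of line 103, 0 were higher and 0 lower (818 at an unadjusted p under 0.05). Without the transgenic library of line 104 fewer genes were called higher and more were called lower. Both counts fell without either sibling library. Each of these fits leaves 1 library in a group.

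The fragments recovered from the FPKM steps were an alternative chosen after seeing the data. With limma-voom they gave 2 genes higher and 3 lower of 14286, and 83 higher and 114 lower with the line as block. The blocked fit has 1 residual degree of freedom. Its prior degrees of freedom, the weight of the variance shared across genes, were 98.8, against 8.27 without the block. Its small p-values thus rest mostly on that shared variance and little on each gene's own spread. The P0 gene Solyc06g076870 (145 and 172 against 10 and 10 fragments; limma-voom adjusted p = 3.89e-09 with the block) was the 1 gene called both by the FPKM test and by this blocked fit. No other gene called by the FPKM test had fragments read as a longer transcript and could enter this fit, so the overlap could not be larger. With the block, all 8 floral organ identity genes passed over all genes, TAP3 with 838 and 585 fragments in transgenic against 115 and 47 in sibling tips of lines 103 and 104 (limma-voom adjusted p = 1.14e-13). J2, EJ2, FUL2 and WUS also passed. Without the block, neither these genes nor any of the 8 floral organ identity genes passed. The smallest limma-voom adjusted p among them was then 0.0736, for TAP3. It was 0.274 for J2 and EJ2, 0.405 for FUL2 and 0.496 for WUS. Annotated genes with large rises in the blocked fit included an ent-kaurenoic acid oxidase gene of gibberellin synthesis, Solyc10g007860 (513 and 334 against 9 and 13 fragments), and Solyc06g064480, annotated TAP1 (836 and 23 against 0 and 1 fragments). Without the block the limma-voom adjusted p was 0.0316 for Solyc10g007860 and 0.999 for Solyc06g064480. Among those with large falls were patatin-like protein 3, Solyc02g065090 (0 and 1 against 28 and 50 fragments), and an alpha-glucosidase-like gene, Solyc03g094020 (16 and 66 against 200 and 639 fragments). For these the limma-voom adjusted p without the block was 0.0468 and 0.185. Of 91 defence genes with recovered fragments, 14 fell and 0 rose over all genes in the blocked fit. Adjusted over the list alone, 20 fell and 2 rose with the block, and 11 fell and 0 rose without it.

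The libraries of the 2 lines also differed. Between lines 104 and 103, over both genotypes, limma-trend called 212 genes, 38 higher and 174 lower in line 104. Leaving out 1 library gave 29 genes without the transgenic and 37 without the sibling library of line 103, and 0 without either library of line 104. The libraries of line 103 also stood apart in the sum of their FPKM values. Their FPKM values summed to 9647292 (transgenic) and 16044132 (sibling), against 3614310 and 3942452 in line 104, and their 10 highest transcripts held 70.7% and 75.8% of the sum, against 32.2% and 41.1%. An FPKM sum is not a share of fragments, since each value is scaled by the transcript's length. Solyc11g027630 alone was at 4270000 FPKM in the transgenic and 7670000 FPKM in the sibling library of line 103. Each line is also a library pair, so family and library effects cannot be separated in this comparison. The fold changes of the 2 lines were uncorrelated across the tested genes (Pearson's r = -0.0048; genes are not independent replicates). Across the genes with recovered fragments r was 0.19.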

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

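The tests in this part, except that of transcript length, were chosen after the results were seen. In each of the first 5 lists below, the median fold change had one sign in line 103 and the other in line 104. The difference was tested with camera on line 104's change less line 103's, as a contrast of 2 libraries against 2 whose residual holds the genotype and line effects. The median log2 fold change of line 104 less that of line 103 was 1.07 for histones, 0.66 for cytosolic ribosomal proteins, 0.48 for plastid ribosomal proteins, 0.50 for jasmonate and wounding genes and -0.78 for ABA synthesis genes. The adjusted p of the difference was 8.16e-14 for histones and for cytosolic ribosomal proteins, 4.56e-06 for plastid ribosomal proteins, 0.0656 for jasmonate and wounding genes and 0.0601 for ABA synthesis genes. With an estimated correlation these were 0.678, 0.678, 0.436, 0.678 and 0.754 as adjusted p. On recovered fragments the jasmonate and wounding medians had the same sign, -0.16 in line 103 and -0.23 in line 104 (31 genes). The same test called 3 further lists. The difference of medians was -0.27 for cyclins and mitosis (adjusted p = 0.013; adjusted p = 0.971 with an estimated correlation), 0.21 for defence and PR proteins (0.0182; adjusted p = 0.97 with an estimated correlation), both lower in each line, and -0.25 for secondary wall genes (0.0245; adjusted p = 0.97 with an estimated correlation), whose medians were 0.12 and -0.13.

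Histone genes had a median of -0.40 in line 103 and 0.67 in line 104, and cytosolic ribosomal protein genes of -0.38 and 0.28. A candidate explanation is a trend with transcript length that differed between libraries. Only 15 of 56 histone genes and 53 of 212 ribosomal protein genes had recovered fragments and a spliced length, so the check is void and the explanation stays open. In those genes the medians of lines 103 and 104 were -0.28 and 0.63 for histones and -0.20 and 0.27 for ribosomal proteins, of which 88.8% and 70.5%, and 73.8% and 38.8%, were left against genes matched on spliced length and level. Family background, also open, was not tested.

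Most genes called by the FPKM test were listed at 0 in both libraries of 1 group. A candidate explanation is single fragments scaled up by a small effective length. Fragments could be read for 13 of the 27 genes, 48.1%, which is under the 80% set for such a check, so it is void and decides nothing. Among the 12 short transcripts that could be read, the library with the most held at most 2 fragments.

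The rise of the floral organ identity genes in both lines was weighed against library scaling, which would move all genes alike. The median of the 8 genes lay at least 1.95 (log2) above that of all tested genes in each line, which a scaling of all genes alike would not give. The list test had already set these genes against all others. The value therefore restates that result and is no separate evidence. A larger share of floral tissue in the transgenic tips would raise all of these genes, and the smallest ratio among them was 1.95-fold, so this explanation stays open. An effect of the transgene on these genes within the same tissue stays open as well, as the design sets genotype and any difference in stage together.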

How the results depend on the processing

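The recovered-fragment and 500 bp alternatives, and all for Solyc07g006880, were chosen after seeing the data. The causes of the changes given here were not tested. The main counts of 17 higher and 10 lower became 6 and 5 with no filter, 8 and 2 with gene regions of at least 500 bp, and 2 and 3 with recovered fragments. Higher genes numbered 11 at 5 FPKM. With the line as replicate block the counts were 21 and 10 on FPKM, 16 and 6 for regions of at least 500 bp, and 83 and 114 on recovered fragments. Leaving out 1 library gave 0 to 13 higher and 0 to 13 lower. Genes that differed between lines, 212, became 36 with no filter, 48 with recovered fragments, 148 with genotype as a replicate block, 216 with that block for regions of at least 500 bp, 281 with it on recovered fragments, 230 without trend, and 0 to 37 without 1 library. The 11 lists called became 0 with an estimated correlation, with or without the replicate block, and 0 with fry, and were 9 to 14 without 1 library. The correlation between lines, -0.0048, was -0.041 by Spearman, -0.032 at 5 FPKM, 0.020 with a pseudocount of 0.1, 0.076 for regions of at least 500 bp and 0.19 with recovered fragments. The log2 fold change was 9.83 to 10.32 for Solyc07g006880 and 0.03 to 0.36 for the preset SlZFP2 locus without 1 library. The preset locus gave no value at 5 FPKM, and Solyc07g006880 none in the recovered fragments or at 500 bp. Without the transgenic library of line 104 the cytosolic ribosome list was lower (adjusted p = 0.00688) and the histone list turned down (adjusted p = 0.562). Without the transgenic or the sibling library of line 103 the cytosolic ribosome list was higher (adjusted p = 0.00079 and 0.0155), and without the sibling of line 104 its direction was down (adjusted p = 0.207). The histone list kept its upward direction without the other 3 libraries in turn, with adjusted p from 3.47e-06 to 0.921. With the replicate block the seed storage list was lost (adjusted p = 0.076) and the heat shock list gained (adjusted p = 0.0065; adjusted p = 0.858 with an estimated correlation and the block). Low depth limits genes at a few fragments, such as SFT.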

Other observations

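The lists that were not called included the circadian clock (8 tested, adjusted p = 0.410), heat shock (adjusted p = 0.0581), pectin modification (0.0581), secondary wall (0.153), flavonoid (0.151), pollen and anther (0.280), cuticle and lipid transfer (0.307), jasmonate and wounding (0.333), ethylene (0.393), transposon (0.429), cytokinin (0.641), cytosolic ribosome (0.641), plastid ribosome (0.153), cell wall loosening (0.667) and C2H2 zinc finger genes (0.933). Several of these were called as higher at the preset correlation under alternatives. With an estimated correlation the calls on recovered fragments were lost. Camera adjusted p was then 0.591 for pectin modification and 0.592 for secondary wall and for heat shock, and 0.496 for each with the block. With the block it was 0.503 for flavonoid and 0.681 for cuticle and lipid transfer genes. Pectin modification had an adjusted p of 0.0366 without the transgenic library of line 103, 0.000104 without the sibling of line 104, 0.0425 for gene regions of at least 500 bp, and 0.0018 on recovered fragments (0.00229 with the line as block). Secondary wall had 0.000837 without the sibling of line 104 and 0.00601 on recovered fragments (0.00543 with the block). Without the sibling of line 103 both turned down (0.663 and 0.445). Flavonoid genes had 0.0399 without the transgenic library of line 104, 0.0238 for regions of at least 500 bp (0.0153 with the block) and 0.0108 on recovered fragments with the block. Heat shock genes had 0.0065 with the block, and 0.0190 with it for regions of at least 500 bp. On recovered fragments they had 0.0139, and 0.00235 with the block. They had 4.55e-05 without the transgenic library of line 104 and 0.00673 without the sibling of line 103, and turned down without the transgenic library of line 103 (0.667). Plastid ribosome genes had 0.00426 without the transgenic and 0.00417 without the sibling library of line 103, and turned down without either library of line 104 (0.605 and 0.689). Cuticle and lipid transfer genes had 0.0489 on recovered fragments with the block, and jasmonate and wounding genes 0.0327 without the sibling of line 103. Cytosolic ribosome genes had 0.00079 without the transgenic and 0.0155 without the sibling library of line 103, and were lower without the transgenic library of line 104 (0.00688).

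Seed storage genes were called as higher (adjusted p = 0.0203; adjusted p = 0.714 with an estimated correlation), as were histones (adjusted p = 0.00439; adjusted p = 0.760 with an estimated correlation), which had medians of opposite sign in the 2 lines. The seed storage list had an adjusted p of 0.252 without the transgenic library of line 103, 0.749 without the sibling of line 104, 0.076 with the line as block, 0.542 at 5 FPKM and 0.0704 with no filter. It was 0.0731 for regions of at least 500 bp with the block, and 0.217 on recovered fragments (0.273 with the block). The histone list had one of 0.562 without the transgenic and 0.921 without the sibling library of line 104. ABA breakdown and terpene genes had 3 tested members each, too few for the test.

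The split of the 4 libraries that crosses genotype and line called 29 genes, against 27 for genotype and 212 for line. A single transcript, Solyc11g027630, named outside the rule after its values were seen, held the highest FPKM in each of the 4 libraries.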
